A study of Arabidopsis thaliana with 6 samples.

How the data were processed

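Total RNA of Col and epiRIL12 plants was measured on 6 Affymetrix arrays, 3 per genotype, each a sample of its own per the labels. Per the labels' protocols, ribosomal RNA was depleted, the remainder was copied with random primers and amplified, and double-stranded cDNA was fragmented, labelled with biotin and hybridised. A double-stranded target does not keep strand, so a gene and an antisense transcript over it cannot be told apart. The authors deposited 1 log2 expression value per locus and array, 29670 loci in all. Background correction, normalization, summarization, the tools used and the genome build behind the probes are not given in the sources used here. The array medians lay within 6.80 to 6.84 and the quantiles differed between arrays. The authors also deposited a table with a log2 difference and a p-value for each locus, whose test is not given in the sources used here. The p-values of that table are unadjusted, as their spread over all loci shows: 1942 of 29670 lie under 0.05.

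The value table numbers its loci and does not name them, and the authors' deposited table lists as many named loci. The tables were joined by position, which was checked by setting the difference of group means against the authors' log2 difference: Pearson's r over loci was 0.967 in place and 0.166 when shifted by 1 position. In blocks of 500 loci Spearman's rho was 0.835 to 0.945. The median gap between both differences was 0.0406 and the largest 0.756, so the authors' differences come from somewhat other values. The sign of the authors' deposited difference is epiRIL12 minus Col by the same comparison, and all differences here have that direction.

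Locus names were matched to the NCBI RefSeq gene table of assembly TAIR10.1, which served for symbols, gene classes, overlaps and neighbours, and from which no coordinates are given. Of the loci, 29521 matched and 149 did not; 25178 were protein-coding, 3562 pseudogene, 583 transcribed pseudogene and 198 of other classes. The design called for the share of transposable-element genes, but this table has no such class, and the 2 pseudogene classes were used in its place, a choice made after the data were seen. These classes also hold pseudogenes of ordinary genes. The names EVD, CACTA1, ATCOPIA4, ATMU1 and ATGP1 are those in general use for their loci, since the table gives these loci no symbol. Probe sequences were not used here, and cross-hybridisation between copies of repeats, paralogs or overlapping genes stays uncertain for every repeat locus named.

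The samples, the main test, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. Each locus was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, genotype as the one factor, no filter on signal), with Benjamini-Hochberg adjustment over 29670 loci and an adjusted p under 0.05 for a call. The values were already log2, so no pseudocount was needed. Errors of group means are SDs and errors of differences are limma's moderated standard errors; the typical standard error was 0.132. On simulated data of 29670 loci with 200 changed, for this comparison of 3 with 3 arrays, limma recovered 66.2% of changes of size 1 on the log2 scale, 84.8% of size 2 and 98.5% of size 4, with 8 false among 174 calls.

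The named genes were the 12 largest called differences in each direction whose 3 epiRIL12 values lay outside the range of the 3 Col values, up to 4 called members of each list, and 15 genes named whatever their values: MET1, DDM1, CMT3, FWA, SDC, QQS, IBM1, ROS1, EVD, SPO11-1, DMC1, MSH4, FLC, SNC1 and 1 gene that is not reported here. A few list members stand beside them as examples, as do called loci and neighbours in locus order that were chosen after their values were seen. There were 19 lists with 347 entries: 335 were measured and 11 were not. The other entry was left out because the annotation gives its locus to another gene, MEE49 in place of PRD1, and AT5G28626 was renamed SADHU1-3 after the annotation. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the 19 lists. Calls per class were compared with two-sided Fisher's exact tests, and shares have exact (Clopper-Pearson) 95% intervals. The spread over chromosomes and the number of neighbouring calls were tested with 100000 permutations of the calls over loci, and again within classes. These used Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3, and plots matplotlib 3.10.9.

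The alternatives were the replicate number as a block, quantile normalization, median centring, leaving out the lowest 25% or the lower 50% of loci by mean signal, a trended robust eBayes, an ordinary equal-variance two-sample test per gene, adjusted p limits of 0.01 and 0.10, and leaving out each array in turn. Added after the data were seen were the authors' deposited p-values after adjustment, leaving out both arrays numbered 3, permuting within classes, the NLR list without RPP5, and the class and chromosome results without single arrays. No 2 arrays were duplicates: the SD of the log2 difference between arrays of one genotype was 0.334 to 0.366. Scanner files were not used here, and no signal over background can be given.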

Results

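RNA levels were compared between 2 genotypes of Arabidopsis thaliana, the reference accession Col and epiRIL12, with 3 arrays each. An epigenetic recombinant inbred line (epiRIL) descends from a cross of Col with a DNA methylation mutant and carries a mosaic of chromosome segments from both parents; the MET1 gene, mutated in the founder of this family of lines, encodes the enzyme that maintains CG methylation. The series title places the comparison in a study of how lost DNA methylation affects the recombination landscape. Plants were 14 days old, untreated and grown in long days, and the labels name the material both as whole seedlings and as rosette leaves. Expression of 29670 loci was given on a log2 scale. Array medians lay between 6.80 and 6.84, and values ran from 2.30 to 15.5 over the 6 arrays. Across loci, which are not independent replicates, Pearson's r was 0.988 to 0.990 between arrays of one genotype and 0.979 to 0.982 between genotypes. Values were spread a little more widely on both arrays numbered 3 (SD over loci 2.37 and 2.40) than on the other 4 (2.32). Nothing in the labels says whether the 3 samples of a genotype came from separate plantings, so the p-values measure the spread between these samples, and the number of arrays limits their precision.

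Most loci that differed between epiRIL12 and Col were annotated as pseudogenes and had higher RNA levels in epiRIL12. Of the 29670 loci, 264 rose and 25 fell in epiRIL12 (limma, Benjamini-Hochberg adjusted p under 0.05), and 240 of the rises and 12 of the falls were at least 2-fold. The median rise was 5.41-fold (log2 2.44) and the median fall 1.99-fold (log2 -0.99), and 89 loci rose by 8-fold or more. Loci that rose had a median log2 level of 5.07 in Col and 7.55 in epiRIL12, against a median of 6.79 over all loci in Col. No background level was given, so folds from low levels are differences of array values and may not be ratios of RNA. At an unadjusted p under 0.05 there were 2089 loci. With the 50% of loci of lower mean signal left out, 92 rose (89 at least 2-fold), and with both arrays numbered 3 left out, 141 rose (141 at least 2-fold) and 10 fell. An ordinary equal-variance test gave 123 rises (111 at least 2-fold) and 11 falls (5 at least 2-fold). The number of falls was 13 with the replicate number as a block, 10 without epiRIL12 replicate 1, 15 without epiRIL12 replicate 3, 16 without Col replicate 1, 11 at an adjusted p under 0.01 and 39 at 0.10.

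Silent repeats of the Arabidopsis genome are a main site of DNA methylation. The annotation used here has no class for transposable-element genes and places such loci, among them the retrotransposon EVD and the DNA transposon CACTA1, with the pseudogenes. The 2 pseudogene classes held 4145 of the 29670 loci (14.0%) and 237 of the 264 rises (89.8%, exact 95% interval 85.5 to 93.2%; odds ratio 57.3, two-sided Fisher's exact p = 8.4e-171). Thus 5.72% of pseudogene-class loci rose, against 27 of 25178 protein-coding loci (0.107%). Among the falls, 6 of 25 were in these classes (24%, interval 9.36 to 45.1%; Fisher's exact p = 0.149), and 18 were protein-coding. Without Col replicate 3 this share of the falls passed the test (31.6%, Fisher's exact p = 0.0397). With the 50% of loci of lower mean signal left out it was 3 of 17 (17.65%), but that setting kept only 218 class loci among 14835 (1.47%, against 14.0% of all loci), so its Fisher's exact p of 0.00183 is not comparable with 0.149. The median Col level of pseudogene-class loci was 4.32 on chromosome 2 and 4.31 elsewhere, below the lower quartile of every array (4.71 to 4.90). From such levels a locus can hardly fall, so none of these p-values decides whether falls favoured the pseudogene classes. These Fisher tests treat loci as independent, which copies of one repeat family are not.

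Chromosome 2 carried 49.4% of the pseudogene-class rises. Of its 903 pseudogene-class loci, 117 rose (13.0%), against 120 of 3242 on the other chromosomes (3.70%), a ratio of 3.50 (Fisher's exact p = 3.7e-22). The shares were 2.69% on chromosome 1, 3.14% on chromosome 3, 5.23% on chromosome 4 and 3.91% on chromosome 5. Protein-coding rises were also denser on chromosome 2, with 16 of 3887 loci against 11 of 21291 elsewhere (ratio 7.97, Fisher's exact p = 2.4e-07). Over all 289 loci, the uneven spread over the 5 chromosomes gave a chi-square of 215, which no permutation of the calls reached (permutation p = 1e-05, the smallest that 100000 permutations can give). Permuting within the pseudogene classes and within the remaining loci gave a chi-square of 129 and the same p. The comparison of chromosome 2 with the others was chosen after the distribution had been seen. These Fisher tests and permutations treat loci as independent, but 74 of 264 rises had a called neighbour, so their p-values can overstate the evidence. With the 50% of loci of lower mean signal left out, 31 of 65 pseudogene-class loci on chromosome 2 and 51 of 153 elsewhere rose, a ratio of 1.43 (Fisher's exact p = 0.0487). That setting kept 65 of 903 and 153 of 3242 such loci by their mean over both genotypes, so a silent locus could pass it because it rose, and its shares and ratio are not comparable with those over all loci.

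**Figure D1:**
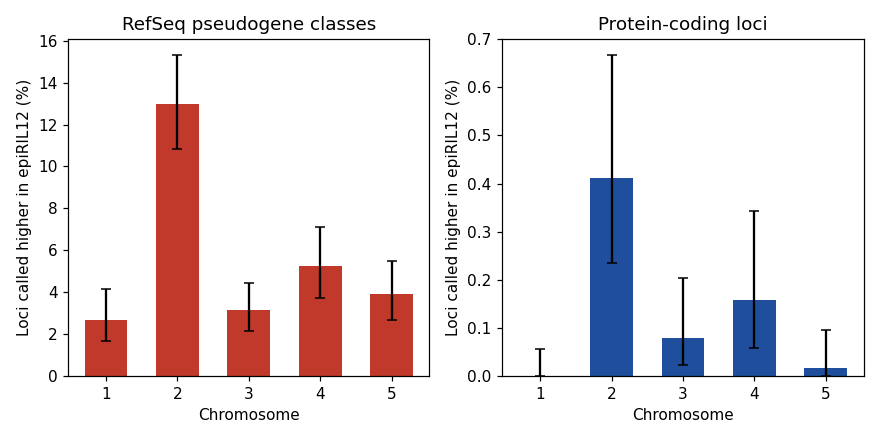
Percent of tested loci that were higher in epiRIL12 than in Col, per chromosome, for the pseudogene classes (left) and for protein-coding loci (right, on a smaller scale); bars are shares and lines exact 95% intervals. Chromosome 2 has the tallest bar in both panels, 13.0% and 0.412%, and no protein-coding locus rose on chromosome 1.

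Loci that rose lay side by side more often than chance placed the calls. In locus order, 39 pairs of neighbouring loci were both among the 289. Permutations over all loci gave a mean of 2.80 pairs and a maximum of 13 (permutation p = 1e-05). Within classes they gave a mean of 9.63 and a maximum of 25 (permutation p = 1e-05). All the pairs were of rises: 74 of 264 rises and 0 of 25 falls had a called neighbour. The permutations did not keep calls on their chromosome, so this excess is not separate from the crowding of rises on chromosome 2. Overlap in the annotation was examined only for pairs of a protein-coding and a pseudogene-class rise, of which SQN and AT2G15800 overlap. For the other pairs, probes or transcripts shared between neighbours were not set apart. Stretches rich in pseudogenes, defined after the data were seen as loci whose surrounding 101 loci were at least 50% pseudogene-class, held 194 of the 264 rises among 3389 loci, against 70 among 26281 elsewhere. Within the pseudogene classes alone, 184 of 2679 loci rose inside these stretches (6.87%) and 53 of 1466 outside (3.62%). On chromosome 2 the loci of these stretches lay from AT2G05420 to AT2G14750, though not every locus between those ends met the definition. Of the 766 that did, 93 rose (12.1%), against 40 of the other 4082 loci of the chromosome (0.980%). Of the pseudogene-class loci alone, 83 of 571 rose among those that met it (14.5%) and 34 of 332 among the others (10.2%). The corresponding stretches held 11 rises among 441 loci on chromosome 1, 28 among 887 on chromosome 3, 32 among 629 on chromosome 4 and 30 among 666 on chromosome 5.

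**Figure D2:**
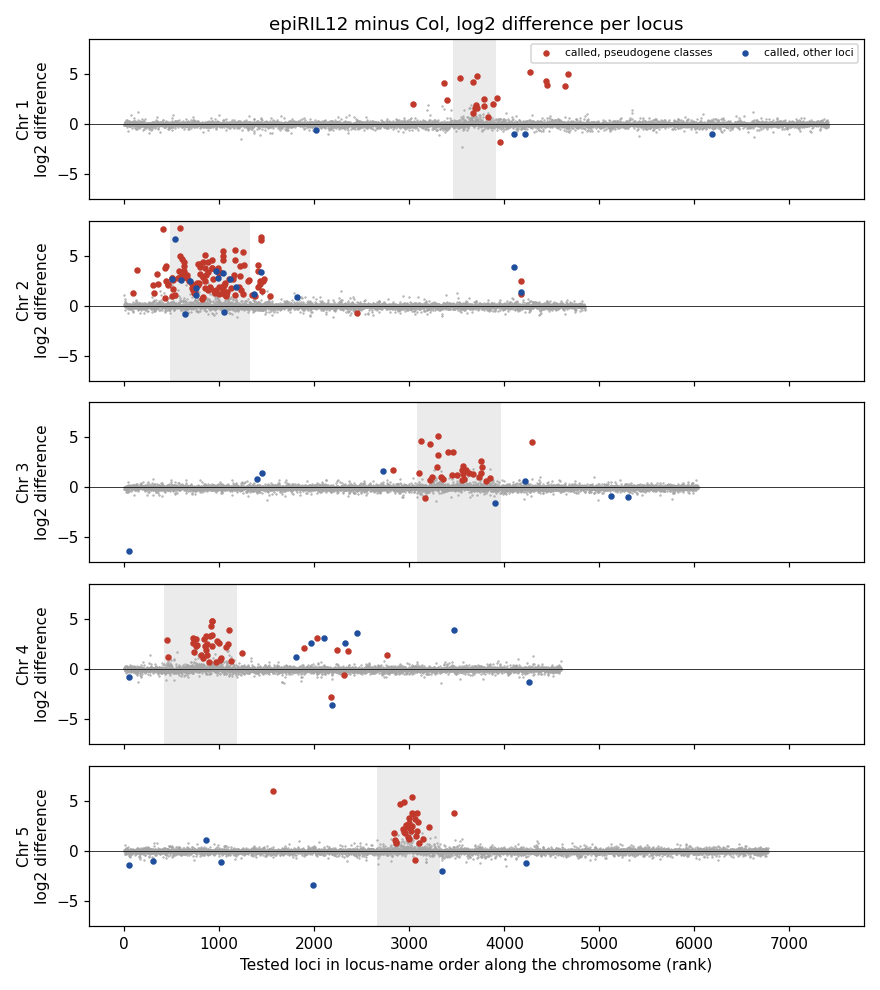
Log2 difference (epiRIL12 minus Col) of each tested locus by its rank in locus-name order along the 5 chromosomes. Red points are loci of the pseudogene classes and blue points other loci, both with an adjusted p under 0.05, and small grey points are all others. Grey bands run from the first to the last locus of the pseudogene-rich stretches and can also hold loci that do not meet their definition. Points above 0 crowd in the band of chromosome 2. Of the loci there that meet the definition 93 rose, 40 rose among the other loci of that chromosome, and 20 on the whole of chromosome 1.

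The strongest rises were at pseudogene loci of chromosome 2. AT2G06370 stood at a log2 level of 5.39 ± 0.39 (SD, n = 3) in Col and 13.2 ± 0.11 in epiRIL12, a 222-fold rise (log2 7.79, SE 0.20). AT2G04770 rose 206-fold (log2 7.68, SE 0.32) between neighbours AT2G04760 and FLA7, at 0.07 and 0.08. AT2G15800 and its neighbour AT2G15810 rose together by 6.91 and 6.58 on the log2 scale. AT2G05915, annotated as protein-coding, rose by 6.69 with a larger error (SE 0.54), since its Col values spread with an SD of 1.198. Among the other 12 strongest rises were AT2G13310 (5.58), AT2G12300 (5.50) and AT2G14230 (5.40) on chromosome 2, AT5G32517 (5.41), AT1G49080 (5.22) and AT3G30767 (5.16). The retrotransposon EVD (AT5G17125), a Copia element known for moving in methylation-deficient lines, rose 63.8-fold, from 4.16 ± 0.15 to 10.2 ± 0.54 (limma adjusted p = 9.3e-05). In Col, EVD, AT2G13310 (4.25) and CACTA1 (4.55) lay below the lower quartile of the arrays (4.78 to 4.89), and no background level was given, so folds from such levels are differences of array values and not measured ratios of RNA. The same limit can hold for the other folds here, since AT2G06370 (5.39) and AT2G04770 (5.98) also lay below the Col median of 6.79. All 12 rises kept their call under the replicate block, the other normalizations and with any single array left out.

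Named genes also fell. The largest fall was at AT3G01345, a protein-coding locus that went from 11.9 ± 0.20 (SD, n = 3) to 5.52 ± 0.32, an 84.4-fold decrease (log2 -6.40, SE 0.19, limma adjusted p = 2.2e-05), while its neighbours AT3G01340 and AT3G01350 stood at 0.10 and 0.04. RPP5 (AT4G16950), an immune receptor gene for resistance to downy mildew, fell 12.3-fold from 11.7 ± 0.07 to 8.12 ± 0.19 (log2 -3.62, SE 0.12, adjusted p = 3.3e-05). NdhU (AT5G21430), which encodes a subunit of the chloroplast NDH complex, fell 10.5-fold (log2 -3.39, SE 0.11). The retrotransposon ATCOPIA4 (AT4G16870) fell 6.98-fold from 8.80 ± 0.12 to 6.00 ± 0.13 (log2 -2.80, SE 0.11), against the direction of EVD and CACTA1. Its Col level lay above the median of 6.79 over all loci, while those of EVD (4.16) and CACTA1 (4.55) lay below it. Smaller falls were those of MRU1 (-2.01), LCR30 (-1.54), a defensin-like gene, AT5G01445 (-1.45), the aminopeptidase gene APP1 (-1.32), the actin-related ARP9 (-1.19) and the pseudogene AT3G29798 (-1.06). The calls of LCR30, AT5G01445 and AT3G29798 were lost under the replicate block (adjusted p 0.0587 to 0.0670), and that of AT3G29798 also without epiRIL12 replicate 1 (0.0524). AT1G44075 (-1.81) lost its call with any of 5 single arrays left out (adjusted p 0.0874 to 0.132), and AT5G11360 (-1.12) with any of the 6, under the block and under quantile normalization (0.0553 to 0.107).

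**Figure D3:**
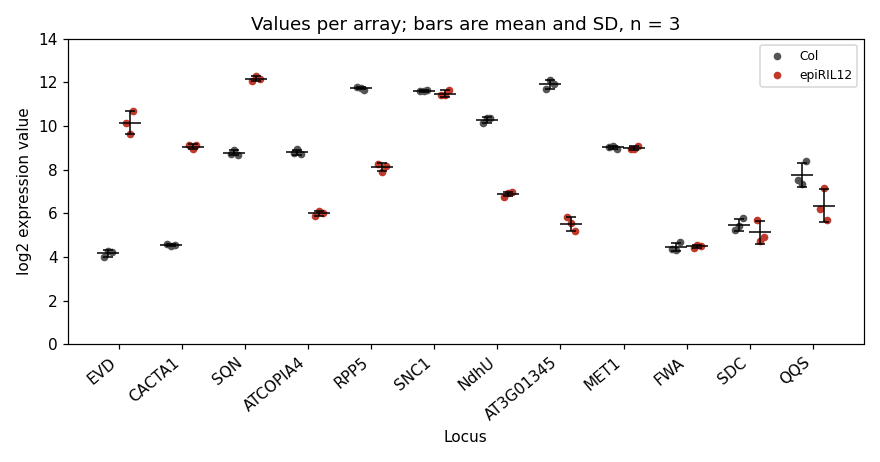
Log2 expression values of 12 loci on each array (grey, Col; red, epiRIL12), with horizontal bars at the mean and vertical bars of 1 SD (n = 3 per genotype). EVD, CACTA1 and SQN, which overlaps the rising pseudogene AT2G15800 in the annotation, lie higher in epiRIL12, and ATCOPIA4, RPP5, NdhU and AT3G01345 lower, while MET1 stands near 9.0 in both genotypes.

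Loci known to respond to lost methylation moved in both directions. Of 13 measured members of that list, 2 rose, 1 fell and 10 did not pass the test over all genes tested; adjusted over the list alone, 2 rose and 2 fell. Beside EVD, the transposon CACTA1 (AT2G12210) rose 22.9-fold (log2 4.52, SE 0.10, limma adjusted p = 7.6e-06), and ATCOPIA4 fell. FWA, a flowering gene silenced by methylation in leaves, stood at 4.46 ± 0.19 (SD, n = 3) in Col and 4.49 ± 0.08 in epiRIL12. SDC, silenced through promoter repeats, stood at 5.48 ± 0.28 and 5.13 ± 0.52. QQS, a starch-related gene with heritable epigenetic variation, stood at 7.77 ± 0.56 and 6.36 ± 0.76 (log2 -1.41, SE 0.43); its adjusted p was 0.476 over all genes, and it was the second fall when adjusted over the list alone. The mean log2 difference of the list was 0.40 and its median -0.08 (camera adjusted p = 0.859, 0.950 with an estimated correlation). The rotation test fry, which asks whether a set's genes move on balance one way and does not compare them with other genes, passed for this list alone (adjusted p = 0.0324). Of the list's members 5 were above 0 and 8 below, and fry was not repeated without EVD, CACTA1 and ATCOPIA4. The pass thus does not show a shift of the list as a whole.

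Transcripts of the methylation machinery showed no called difference over all genes tested. Of 34 measured genes, 1 was below an unadjusted p of 0.05, and 1 fell when adjusted over the list alone. That gene was NRPE1, the largest subunit of RNA polymerase V, which guides RNA-directed DNA methylation (log2 -0.86, SE 0.16, limma adjusted p = 0.0956 over all genes). The log2 difference was -0.03 for MET1 (SE 0.09), 0.02 for the chromatin remodeller DDM1 (SE 0.12), -0.00087 for the methyltransferase CMT3 (SE 0.12) and -0.15 for the histone demethylase IBM1 (SE 0.11). The list's mean difference was -0.05 (camera adjusted p = 0.709). All 4 DNA demethylase genes had values below 0 and none was called, also over the list alone; ROS1, which removes methylation, had a log2 difference of -0.37 (SE 0.15, limma adjusted p = 0.706), and the list's camera adjusted p was 0.370.

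The recombination question in the series title led to a list of meiotic recombination genes. None of its 32 measured members was called, over all genes or over the list alone, and 2 were below an unadjusted p of 0.05. The mean log2 difference was -0.06, with 20 members below and 12 above 0 (camera adjusted p = 0.478). The nuclease gene SPO11-1, which makes the breaks that start meiotic recombination, stood at 4.23 ± 0.51 (SD, n = 3) in Col and 4.27 ± 0.05 in epiRIL12. Both levels lay below the lower quartile of every array (4.71 to 4.90), and no background level was given, so a difference might not be seen there. The log2 difference was 0.08 for the strand-exchange gene DMC1 (SE 0.13) and -0.02 for MSH4 (SE 0.20), which acts in crossover formation. HEI10, a dosage-sensitive crossover gene, had the lowest value of the list, -0.66 (SE 0.19, limma adjusted p = 0.440), and the strand-invasion cofactor gene MND1 was the other member below an unadjusted p of 0.05 (0.33, SE 0.13, adjusted p = 0.682). Both were singled out after their values were seen. Seedlings and leaves hold few if any meiotic cells, and the list's genes are measured there outside meiosis.

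Among lists for the state of the plant, 3 passed camera with its preset correlation, cell cycle and DNA replication genes upward and circadian clock and NLR immune receptor genes downward in epiRIL12. None of the 3 passed with an estimated correlation (adjusted p = 0.950 for each) or with fry (0.831, 0.229 and 0.151). Of 15 measured cell cycle genes, 14 were above 0, with a mean log2 difference of 0.16 (camera adjusted p = 0.00742, but 0.950 with an estimated correlation); the mitotic kinase gene AUR2 had 0.44 (SE 0.17) and the replication gene MCM5 0.20 (SE 0.10). Of 17 clock genes, 14 were below 0, with a mean of -0.16 (camera adjusted p = 0.0179, but 0.950 with an estimated correlation), among them LUX (-0.31, SE 0.12) and GI (-0.22, SE 0.10). No cell cycle or clock gene was called, over all genes or over the list alone. Of 13 NLR genes, 11 were below 0 with a mean of -0.37 (camera adjusted p = 0.0179, but 0.950 with an estimated correlation), and 1, RPP5, was called, over all genes and over the list alone. Without RPP5 the mean of the NLR list was -0.09 (camera adjusted p = 0.323), and SNC1, in the RPP5 cluster, had a log2 difference of -0.14 (SE 0.10). Over the settings tried, 0.950 was the highest adjusted p of each of the 3 lists, and the lowest were 2.1e-05 for the cell cycle, 0.00431 for the clock and 0.000456 for NLR genes. With 1 array left out at a time the number of lists past the test ran from 0, without Col replicate 3 or epiRIL12 replicate 1, to 5, without epiRIL12 replicate 3, and it was 1 without Col replicate 1, the seed markers, and 1 without epiRIL12 replicate 2, the cell cycle genes.

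The remaining lists of defence, stress, hormone and metabolic genes showed no called member, over all genes or over the lists alone. The mean log2 difference was 0.06 for 23 salicylic acid defence genes (camera adjusted p = 0.859), 0.0079 for 17 heat shock genes (0.859) and -0.08 for 14 genes of the cold, drought and abscisic acid response (0.490). DNA damage response genes had a mean of 0.06 over 19 members (0.709), flavonoid and anthocyanin genes 0.03 over 14 (0.478) and glucosinolate genes -0.07 over 20 (0.351). For 20 jasmonate genes the mean was -0.04 and for 21 photosynthesis genes -0.01 (0.859 each), though camera ranked both lists upward. Flowering time genes had a mean of 0.0024 and a median of -0.05 over 17 members (0.859), with FLC, the floral repressor, at 5.89 ± 0.47 (SD, n = 3) in Col and 5.84 ± 0.59 in epiRIL12. Markers of other tissues were not called either. The mean was -0.03 for 18 root markers and -0.04 for 13 floral organ and pollen markers (0.859 each, ranked upward by camera) and 0.14 for 11 seed markers (0.248). With an estimated correlation, the adjusted p was 0.950 for each of these lists too. At an unadjusted p under 0.05 each list held 0 to 2 members. With 1 array left out, 2 of these lists passed camera upward: flavonoid and anthocyanin genes without epiRIL12 replicate 3 (adjusted p = 0.00665; 0.00665 to 0.984 over all settings) and seed markers without Col replicate 1 (0.0108) or epiRIL12 replicate 3 (0.0279; 0.0108 to 0.965 over all settings).

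The authors' deposited table gives its own log2 difference and unadjusted p for each locus. After Benjamini-Hochberg adjustment, the p-values of the authors' deposited table put 138 loci under 0.05, 123 higher and 15 lower in epiRIL12. Of these 138, 126 were also called here, all 126 in the same direction, and 12 were not; 163 loci were called here alone. All 289 loci called here had the same sign in the authors' deposited table, and 286 had an unadjusted p under 0.05 there. Both sets of differences describe the same comparison, and the tables were joined on their agreement, so the shared signs are no independent evidence. For EVD the authors' deposited table has a log2 difference of 5.84, and for RPP5 it has -3.58.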

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

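The setting without both arrays numbered 3, the authors' deposited p-values, and the class and chromosome values without single arrays were chosen after the data were seen. Under the tried settings 84.4 to 95.5% of calls were higher, and none of the 25 called named genes changed sign; of their 295 alternative values, 278 kept the call and 17 lost it. None of the 14 named genes without a call gained one, though several with differences near 0 changed sign. The 264 rises became 92 (89 of 240 at 2-fold) without the 50% of loci of lower signal, where fewer loci were tested and a locus could pass because it rose, 123 (111) with the equal-variance test, which does not share spread between loci, 141 (141) without both arrays numbered 3 and 123 with the authors' p-values. The 25 falls became 11 (5 of 12 at 2-fold) with the equal-variance test, 10 without both arrays numbered 3, 15 with the authors' p-values, 11 at an adjusted p under 0.01 and 39 at 0.10. With 1 array left out, rises numbered 197 to 220 (2-fold 189 to 208) and falls 10 to 19 (2-fold 10 to 17): 10 without epiRIL12 replicate 1, 15 without epiRIL12 replicate 3 and 16 without Col replicate 1. The number of lists past camera, 3, became 0 with an estimated correlation, 1 with fry (methylation-sensitive loci, not among the 3) and 0 to 5 with 1 array left out: 0 without Col replicate 3 or epiRIL12 replicate 1, 1 without Col replicate 1 (seed markers, not among the 3), 1 without epiRIL12 replicate 2 (cell cycle), and 5 without epiRIL12 replicate 3 (the 3, flavonoid genes and seed markers). The pseudogene-class share of the falls, 24%, was 17.65% (Fisher's exact p = 0.00183) without the 50% of loci of lower signal, where class loci were 1.47% of those tested and not 14.0%, so this p is not comparable with 0.149, and 10% to 31.6% with 1 array left out, past the test only without Col replicate 3 (p = 0.0397). Beyond fewer loci or arrays, the cause was not tested. With the replicate number as a block (replicate block), 197 rose and 13 fell. Deviations of same-numbered arrays correlated at -0.04, -0.07 and 0.13, and not every array correlated best with its own number. The labels give same-numbered arrays only the number in common. Both arrays numbered 3 also had a wider spread over loci (SD 2.37 and 2.40, against 2.32), and whether they were handled together is not known. The share of rises in the pseudogene classes and the uneven spread over chromosomes passed under every setting tried for them. No pseudocount was varied, as values were log2. Signal over background was not given, so what dim signal limits was not assessed; 12 of 25 falls and 13 of 264 rises started above the median Col level.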

Other observations

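The loci and regions of the next 2 paragraphs were chosen after their values were seen, as were the tests of chance placement, of hybridisation between copies and of SQN, and the splits of the arrays for counts of loci. In the RPP5 cluster of immune receptor genes, 2 loci fell and the others did not pass the test. From AT4G16860 to AT4G16960, 11 of 12 loci had values below 0, but only RPP5 (log2 -3.62) and the retrotransposon ATCOPIA4 (-2.80), which lies between RPP4 and SNC1 in locus order, were called. RPP4 stood at -0.20 (SE 0.11) and SNC1 at -0.14 (SE 0.10), and AT4G16960, next to RPP5, at -0.94 (SE 0.21, limma adjusted p = 0.198). The neighbours of NdhU, CIPK26 and CKX7, had log2 differences of -0.10 and 0.11, and those of MRU1, AT5G35475 and AT5G35495, had -0.39 and -0.71, none of them called.

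Outside the pseudogene classes, 27 protein-coding loci rose. SQN (AT2G15790), a cyclophilin gene that promotes microRNA activity, rose 10.6-fold from 8.78 ± 0.12 (SD, n = 3), to 12.2 ± 0.10 (log2 3.40, SE 0.11, limma adjusted p = 2.8e-05). ESM1, a gene that steers glucosinolate breakdown, rose 1.75-fold from a high level of 13.04 (log2 0.81, SE 0.08). Chromosome 4 had 6 such rises, all outside its pseudogene-rich stretch, among them AT4G29200 (3.92) and AT4G19240 (3.59). AT2G40955 rose by 3.86 on chromosome 2 outside its pseudogene-rich stretch, while its neighbours BZIP17 and AT2G40960 stood at 0.14 and -0.29. Among smaller falls were the cell wall gene XTH4 (-0.89, SE 0.13), the phosphatase gene 5PTASE11 (-0.98, SE 0.13) and MBD3 (-0.75, SE 0.10), named for a methyl-CpG-binding domain. Of the elements outside the lists, the retroelement SADHU8-1 (AT1G50735) rose by 4.28 (SE 0.19), while SADHU1-3, in the list, had a log2 difference of -0.04 (SE 0.15).

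Pseudogene-class rises were denser on chromosome 2 than elsewhere. Chance placement of single loci among the same classes is argued against by the permutations (p = 1e-05, the smallest they can give). They treat loci as independent, which neighbours and copies of a repeat family are not, so chance placement in groups stays open. A smaller spread between arrays is argued against by the share of loci with a log2 difference of at least 1. It was 15.0% on chromosome 2 against 4.90% elsewhere (ratio 3.05), at a median SD within genotypes of 0.207 and 0.201. Hybridisation between copies of repeats stays open: 16 of the 27 rises outside the classes (59.3%) were also on chromosome 2, but of these only SQN has a symbol of its own, the others may be repeats too, and probe sequences were not used here. A candidate biological explanation, not tested here, is that epiRIL12 carries more of chromosome 2 from its methylation-deficient parent than of the other chromosomes.

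Rises outnumbered falls, 264 to 25. An offset left by the normalization is argued against by the median of all log2 differences, -0.02, against a median rise of 2.44. With arrays so close, median centring and quantile normalization could hardly change the split, and 90.9% and 92.3% of calls were higher after them. Low signal in Col, which leaves a locus less room to fall, may account for part of the imbalance and stays open. Among calls above the median Col level, 13 rose and 12 fell (52% higher, exact 95% interval 31.3 to 72.2%), against 251 and 13 at or below it. About as many falls thus began at low as at higher levels. Loss of silencing at loci that are off in Col would start from the same low levels, so it cannot be told apart from a limit on falls by these counts.

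Of the 27 protein-coding rises, 5 had a pseudogene-class neighbour that also rose, against 1.39 expected for placements in the same chromosome and kind of stretch (permutation p = 0.00623). Without SQN it was 4 of 26 against 1.38 (permutation p = 0.0348). The placements drew on all protein-coding loci of the same chromosome and kind of stretch, while the rises on chromosome 2 other than SQN may be repeats too. The counts exceed those of such loci, less strongly without SQN. They do not decide whether a shared chromosome and kind of stretch alone would place repeats so. A shared smaller region stays open, since the placements did not match the local density of rises. Probes shared through overlap of annotated genes are argued against for the 4 pairs other than that of SQN, of which 0 overlap in the annotation (AT2G05642, AT2G11405, AT2G12290 and AT2G41590 with their neighbours). Probes that match both loci of a pair by sequence stay open, since probe sequences were not used here. SQN and AT2G15800 do overlap and rose by 3.40 and 6.91, so that for SQN a rise of its own and probes or transcripts shared with its neighbour cannot be told apart without the positions of the probes. Transcription running on from an active element into the gene beside it is a possible explanation that was not tested.

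Of the 10 ways to split the 6 arrays into 3 and 3, only 1, the real one, gave as many rises (264, highest other 0), falls (25, highest other 0), 2-fold rises (240, highest other 0) or 2-fold falls (12, highest other 0); 10 splits are too few for a share under 0.05. For the gene lists past camera with the preset correlation, 7 of 10 splits gave at least the 3 of the real one, and the highest other gave 7.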
